A study of Homo sapiens with 6 samples.

How the data were processed

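The series holds 6 RNA sequencing libraries of human mesenchymal stem cells, which are stromal progenitor cells grown from a donor's tissue. The titles place 3 libraries in a group of control cells and 3 in a group carrying introduced AVIL, the gene for advillin, an actin-binding protein of the gelsolin and villin family. Per the labels' protocols, cells were infected with an AVIL virus and stable cells were selected with G418, RNA was taken with Trizol, and libraries were made with an Illumina TruSeq kit from total RNA. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical. The labels name no batch.

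The values used are those of 1 comparison table that the authors deposited. Per the submitters' processing notes, STAR, hg38 and featureCounts 1.6.2 were used. How multi-mapped reads, strand and alternate loci were treated is not given in the sources used here. The column headings are those of a DESeq2 results table made by the authors; the tool itself is not named in the sources used here. Per the file headers, the deposited columns hold the mean over all libraries of the normalized count (a signal value per gene, with counts scaled by library factors), the log2 fold change with its standard error on the log2 scale, the Wald statistic (a score), the p-value and the adjusted p-value. The deposited score equalled the deposited log2 fold change divided by its standard error. No per-library values were analysed here, so the depth of each library is unknown and no counting interval was set. The header does not name the numerator of the ratio. AVIL has a positive value, and positive values are read throughout as higher in the cells with introduced AVIL; if the ratio were the other way, every direction would turn.

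Each of the 831 gene IDs in the table had an absolute log2 fold change above 5, a fold of 32, so the table holds only the largest changes. It was not filtered on the adjusted p-value, which reached 0.187. A gene that is not listed may have changed by less, may not have been tested or may be missing for another reason, so no statement was drawn on any single unlisted gene. A refit across genes was not made, because the values are the authors' own comparison of selected genes. The authors' adjusted p-values were used at a threshold of 0.05.

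The following were computed from the table. The number of tests behind the adjusted p-values was recovered from the ratio of p-value to adjusted p-value, which is a whole rank divided by the number of tests under Benjamini-Hochberg adjustment. With 17209 tests, the rank came out whole within 0.001 for 94.6% of the 827 IDs with a p-value above 0. On simulated data the number was recovered exactly in 5 of 5 tables. Group means were implied from the overall mean and the fold change, under the assumption that the mean covers 3 libraries of each group; they carry no error. Where the implied mean of the lower group was under 1 normalized count, the deposited fold change depends on how the model treats counts near 0 and is no measured ratio. Gene positions came from GENCODE release 29 on the same hg38 assembly, matched by Ensembl gene ID, which placed 762 of the 831 IDs. The other 69 IDs lie outside that primary assembly annotation.

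Before the data were examined, 31 gene lists, the tests and the rule for naming genes were fixed. The rule names AVIL, then the 6 largest rises and 6 largest falls and the 4 smallest adjusted p-values in each direction among IDs with a symbol and a mean at or above the median of those past the threshold, then up to 4 members of each list with the smallest adjusted p. Only 5 falls met these conditions. A gene that the rule names may be left out where it is not reported here. The condition on single libraries in this rule could not be applied. For each list with at least 3 listed IDs, the split into higher and lower was compared with that of the other listed IDs by an exact two-sided Fisher test. After the table was seen, a one-sided hypergeometric test was added, with Benjamini-Hochberg adjustment over the 31 lists. It asked whether a list had more members listed past the threshold than a random draw of 757 symbols from 17209 tested IDs would give. Counts of list members cover listed members only, since changes of up to 32-fold are not seen. The test counts every member as tested, which makes it conservative in that respect. It also draws symbols from IDs although some symbols stand under several IDs, which makes calls easier. Genes that are off in the control cells can reach a 32-fold change more easily, which the test does not correct for. It treats genes as independent. Tested on simulated lists of 25 genes with the same 757 of 17209 draw, at an unadjusted p of 0.05, it called 1.9% of lists of no effect and 92.0% of lists planted at 6 times the chance share. The lists of no effect follow the test's own draw, so they cannot show these biases. A count adjusted over the list alone was not made, because it needs the p-values of unlisted members. Rises and falls were compared in size by a two-sided permutation test of medians over 100000 resamples. Alternatives were adjusted p thresholds of 0.01 and 0.001, Bonferroni adjustment, leaving out the lowest 25% of IDs by mean, and counts without doubtful IDs. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.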

Results

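The transcriptomes of human mesenchymal stem cells with introduced AVIL and of control cells were compared, with 3 libraries in each group. The series title places the comparison in work on rhabdomyosarcoma, a soft tissue tumour with features of immature skeletal muscle. The deposited table lists 831 Ensembl gene IDs under 766 symbols, each with a fold change above 32 in one direction or the other. Its header does not name the numerator, and positive values are read as higher with introduced AVIL because the value of AVIL itself is positive. Mean normalized counts over all libraries ran from 2.75 to 26970 in the authors' deposited table. Library totals were not analysed here, so the depth behind these means is unknown.

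AVIL itself was the most abundant gene listed. In the authors' deposited table its mean normalized count was 26970 and its log2 fold change was 9.50 with a standard error of 0.54, a fold of 723 (authors' adjusted p = 5.64e-68). The implied group means were 53866 normalized counts with introduced AVIL and 74.5 in the control cells. AVIL (ENSG00000135407) lies on the minus strand of chromosome 12 from 57797376 to 57818704 in hg38. Its reads count the introduced and the cells' own gene together. None of the other 7 members of the gelsolin and villin family, which sever and cap actin filaments, is listed.

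Most of the listed genes were higher in the cells with introduced AVIL. Of the 816 IDs past the authors' adjusted p of 0.05, 787 rose and 29 fell, so that 96.4% were higher. At an unadjusted p under 0.05 the numbers were 791 and 30. Beyond the listed genes, the deposited adjusted p-values place between 9606 and 9768 of 17209 tested IDs past the threshold, which is 55.8% to 56.8% of the tests. For 551 of the 787 rises the implied control mean was under 1 normalized count, so their fold changes are not measured ratios. The count of rises was 236, and that of falls 3, among IDs whose implied means reached 1 in both groups. Counted by sets of identical values, since some genes stand under several IDs, 758 rises and 29 falls remained.

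**Figure D1:**
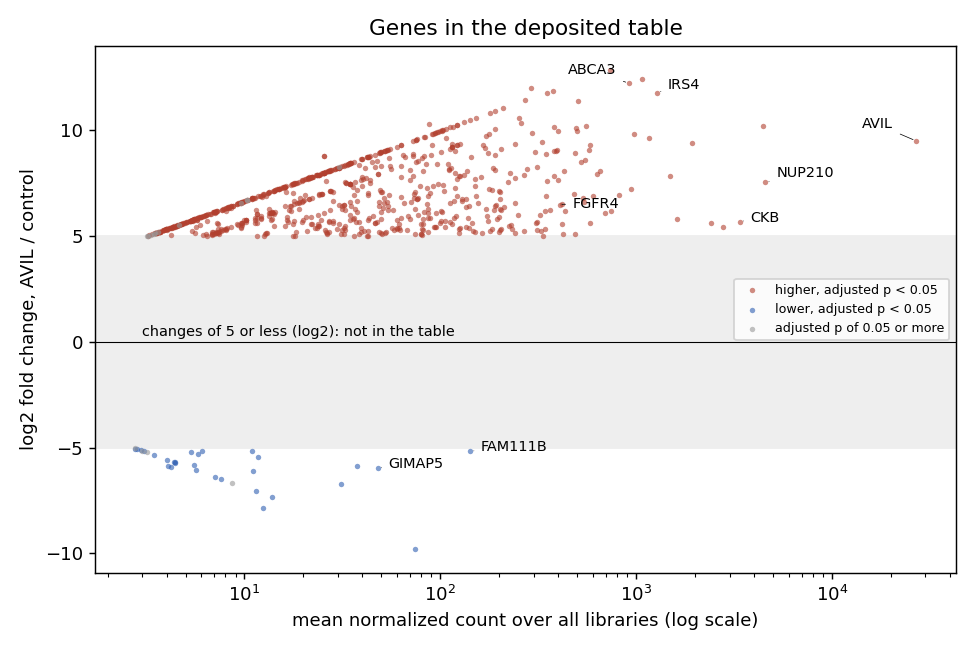
Log2 fold change of each of the 831 listed IDs, AVIL over control, against its mean normalized count over all libraries on a log scale; each point is 1 ID, coloured by direction and by the authors' adjusted p. Points above the grey band (787 past the threshold) far outnumber those below it (29), and the straight upper edge holds IDs whose control level was close to 0.

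The rises with the smallest p-values were in genes with measurable control levels. NUP210, a nuclear pore membrane protein (chromosome 3, 13316235 to 13420309), rose by a log2 fold change of 7.54 with a standard error of 0.16 in the authors' deposited table, a fold of 186. AMOT, the angiomotin scaffold of cell junctions (chromosome X, 112774503 to 112840815), rose 56.8-fold in the same deposited table, with a log2 standard error of 0.15. The brain-type creatine kinase CKB (chromosome 14, 103519659 to 103523111) rose 51.7-fold and the cystathionine beta-synthase CBS (chromosome 21, 43053191 to 43076943) rose 49.3-fold, each with a log2 standard error of 0.12 in the authors' deposited table. The adjusted p of these 4 genes is given there as 0. CBS has a near-identical copy in hg38, CBSL, so its reads could be split.

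The largest deposited log2 fold changes belonged to genes close to 0 in the control cells. ABCA3, a lipid transporter (chromosome 16, 2275881 to 2340746), had a value of 12.23 with a standard error of 1.18 in the authors' deposited table, and an implied mean of 1840 normalized counts with introduced AVIL against 0.38 in the control. IRS4, an adaptor of insulin receptor signalling (chromosome X, 108732482 to 108736409), had 11.79 with a standard error of 1.02 in the authors' deposited table, and an implied mean of 2558 against 0.72. WNK2, a kinase that acts on ion transport (chromosome 9, 93184916 to 93320572), had 11.78 in the authors' deposited table. The mitochondrial creatine kinase CKMT1A (chromosome 15, 43692886 to 43699222) had an implied mean of 584 normalized counts with introduced AVIL against 0.14 in the control. CKMT1A has a near-identical neighbour, CKMT1B, which is also listed, so the division of reads between them is uncertain. HSPA1B, a heat shock protein with a near-identical paralogue and the only listed member of the heat shock list of 21 genes, had a deposited value of 12.84 under an ID outside the primary assembly annotation and 9.82 under another such ID. PPT2, a lysosomal thioesterase at 32153441 to 32163680 in the major histocompatibility complex (MHC) of chromosome 6, had 11.88 in the authors' deposited table. Values for MHC genes and for IDs outside the primary assembly can depend on which copy of a locus the reads match.

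Few genes were listed as lower, and mostly at low levels. Falls of up to 32-fold would not be seen. FAM111B, a serine protease of the nucleus (chromosome 11, 59107185 to 59127410), was the fall with the smallest adjusted p, with a log2 fold change of -5.16 and a standard error of 0.37 in the authors' deposited table (authors' adjusted p = 7.77e-43), 35.8-fold lower. Its implied means were 277 normalized counts in the control and 7.72 with introduced AVIL. GIMAP5, a GTPase best known from lymphocytes (chromosome 7, 150722253 to 150750033), fell by 5.95 with a standard error of 0.76 in the authors' deposited table, from an implied 94.4 to 1.53 normalized counts. The mucin MUC12 fell by 6.71 with a standard error of 2.41 in the deposited table, to a level near 0 (authors' adjusted p = 0.0115). MUC20 fell by 9.77 and ARMC10 by 5.87 in the authors' deposited table, both under IDs outside the primary assembly annotation. CCL7, a monocyte-attracting chemokine and the only listed member of the inflammation list of 43 genes, fell by 7.35 with a standard error of 1.40 in the deposited table, also to a level near 0 (authors' adjusted p = 5.72e-07).

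Rhabdomyosarcoma-associated genes and the muscle programme were represented by a small number of members. Of 27 rhabdomyosarcoma genes, 4 were listed as higher past the threshold and none as lower. Changes of up to 32-fold in the other members would not be seen. FGFR4, a fibroblast growth factor receptor, rose by a log2 fold change of 6.51 with a standard error of 0.38 in the authors' deposited table, a 91.0-fold rise to an implied 826 normalized counts. LIN28B, a regulator of let-7 microRNAs, rose 42.5-fold in that deposited table. It is also a marker of the embryonic kidney line HEK293, of which 5 of 9 markers, chosen after the table was seen, were listed as higher. The transcription factors OLIG2 and PAX7 had log2 values of 8.58 and 6.53 in the authors' deposited table, from control levels near 0; the call of PAX7 was lost under Bonferroni adjustment over the recovered tests. IGF1R, named after its value was seen, stands in the deposited table at 5.53 with a standard error of 3.04 and did not pass the threshold (authors' adjusted p = 0.110). Chance would place 1.19 members of this list among the listed genes past the threshold, and the list was not over-represented there after adjustment (hypergeometric test, adjusted p = 0.301, unadjusted p = 0.0291). Of 37 genes of the myogenic programme, 3 were listed as higher past the threshold: the master regulator MYOD1, the slow-muscle troponin TNNC1 and the calcium channel RYR1. Their deposited log2 fold changes were 5.78, 5.38 and 5.15, with standard errors of 1.67, 1.47 and 1.26, at mean normalized counts of 5.47, 8.16 and 12.8. Each of the 3 calls was lost under Bonferroni adjustment over the 17209 recovered tests. With 1.63 members to be listed past the threshold by chance, the hypergeometric test gave an adjusted p of 0.763 for this list.

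Genes of the Hedgehog and Notch pathways were the only list of the 31 that was over-represented among the listed genes past the threshold after adjustment. Of its 22 genes, 6 were listed as higher and none as lower, against 0.968 to be listed past the threshold by chance (hypergeometric test added after the table was seen, adjusted p = 0.00897). In the same comparison, 5 of 9 marker genes of the embryonic kidney line HEK293, a list written after the table was seen, were also listed as higher, against 0.401 to be had by chance (hypergeometric test, unadjusted p = 1.87e-05). Because that list was written with these values known, its p and chance share are descriptive and test nothing. SMO, the signal transducer of the Hedgehog pathway, was the only Hedgehog gene among the 6. It rose 47.1-fold, with a log2 standard error of 0.26 in the authors' deposited table. The Notch target genes HEY1, HEY2 and NRARP had log2 fold changes of 6.99, 5.79 and 5.56 with standard errors of 0.90, 0.82 and 0.64 in the authors' deposited table. HES4 and DLL1, named after their values were seen, also belong to the Notch pathway. Their deposited log2 fold changes were 9.62 and 5.11, with standard errors of 1.56 and 1.90. The call of the list therefore rests mostly on Notch genes and does not speak for the Hedgehog pathway. With the authors' adjusted p held under 0.01, the call of the Hedgehog and Notch list was lost in the hypergeometric test (adjusted p = 0.0580; 0.00202 to 0.0187 under the other alternatives).

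Of 36 growth factor genes and receptors, 6 were listed as higher and none as lower, against 1.58 to be listed past the threshold by chance (hypergeometric test, adjusted p = 0.0693). Besides FGFR4, this list held FGFR3 and FGFR2, with log2 fold changes of 9.04 and 6.77 and standard errors of 0.73 and 0.61 in the authors' deposited table. IGFBP2, a binding protein of insulin-like growth factors, rose 249-fold in the authors' deposited table, to an implied 1254 normalized counts. The list passed the threshold only when the lowest 25% of IDs by mean was left out (hypergeometric test, adjusted p = 0.0177; 0.0580 to 0.134 under the other alternatives).

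Among 27 Wnt pathway genes, NKD2, LGR5 and NOTUM were listed as higher, with log2 fold changes of 6.75, 8.30 and 5.59 in the authors' deposited table. The 27 genes of the TGF-beta and BMP list held 3 rises in the deposited table, INHBE at 5.26, ID4 at 6.89 and LEFTY2 at 7.07. Of 25 HOX genes, HOXD10, HOXD11 and HOXB9 were listed as higher, by 6.82, 7.59 and 5.98 in the authors' deposited table, from implied control means of 9.40, 3.62 and 10.1 normalized counts. HOXD13, which is outside this list and was named after its value was seen, rose by 6.56 with a standard error of 0.42 in the same deposited table. None of these lists was over-represented (hypergeometric test, adjusted p = 0.539 for each).

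**Figure D2:**
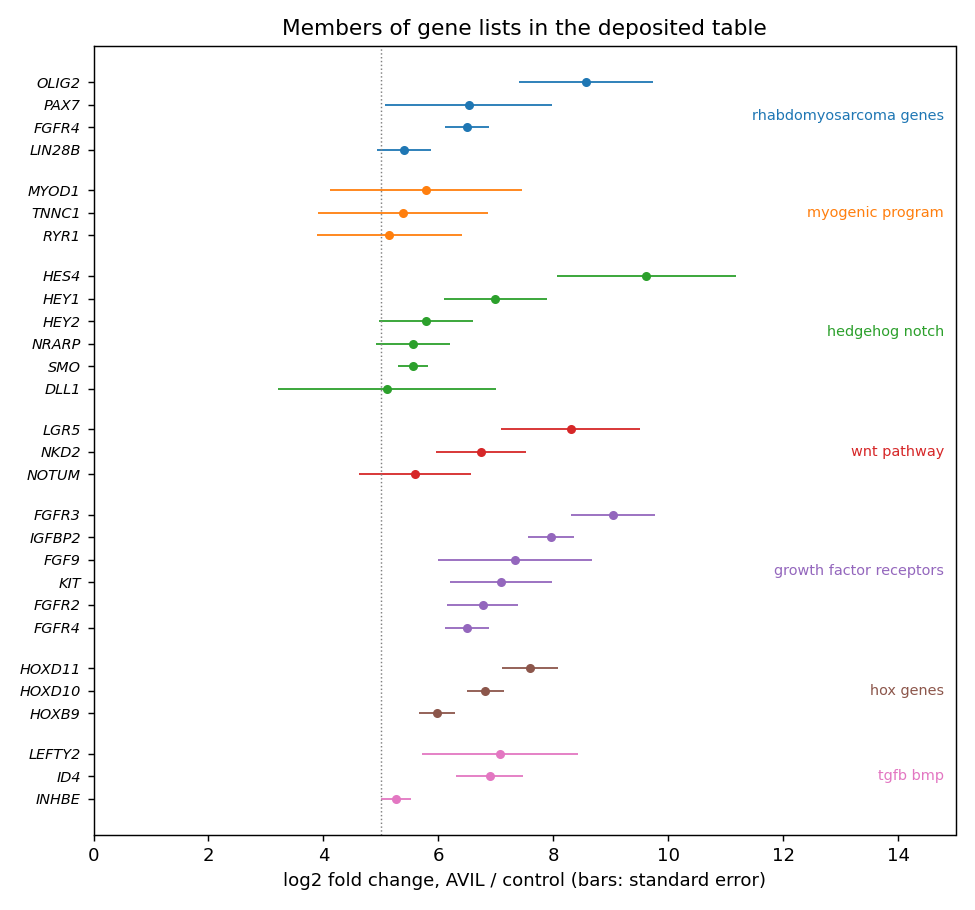
Log2 fold change, AVIL over control, of each member past the authors' adjusted p of 0.05 in the 7 lists with at least 3 listed IDs, including members not named in the text; points are the deposited values and bars their standard errors. Every member drawn is higher in the cells with introduced AVIL, and the dotted line at 5 marks the smallest change that the table holds.

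Differentiation lists of the mesenchymal lineages held few members. COL2A1, the collagen of cartilage, rose 635-fold in the authors' deposited table, with a log2 fold change of 9.31 and a standard error of 0.66, to an implied 1159 normalized counts. The cartilage regulator SOX6 had 5.16, the adipogenic factor CEBPA 5.65 and the bone morphogenetic protein BMP6 5.30 in the authors' deposited table. The calls of SOX6 and BMP6 were lost at an adjusted p under 0.001. These were, with COL2A1, the only members listed past the threshold among 15 chondrogenic, 20 adipogenic and 19 osteogenic genes. No member was listed for 15 of the 31 lists, which include 34 genes of the actin cytoskeleton and adhesion, 18 mesenchymal stem cell markers, 40 extracellular matrix genes, 61 proliferation genes and 48 interferon response genes. Changes of up to 32-fold in these genes would not appear in the table.

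Of 55 markers of other cell types in 4 lists, 4 were listed as higher past the threshold, against 2.42 to be listed past it by chance. Among them, the epithelial cadherin CDH1 had a deposited log2 fold change of 9.24, the synaptic vesicle protein SYP 5.81 and the MHC gene HLA-DRB1 9.34, with implied means of 120, 161 and 252 normalized counts in the cells with introduced AVIL. None of the 4 lists was over-represented (hypergeometric test, smallest adjusted p = 0.539). The 4 lists were not written for the embryonic kidney line HEK293. Of 9 markers of that line, chosen after the table was seen, 5 were listed as higher. The result of the 4 lists therefore does not weigh against RNA of such a line.

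The listed members of every list that had at least 3 listed IDs were higher, and the exact two-sided Fisher test against the other listed IDs called 0 of 7 lists, with a smallest p of 1. Because 96.0% of the 831 listed IDs were higher, this test could not set apart a short list whose members all rose. Rises were larger than falls: the median absolute log2 fold change was 6.52 for the 787 rises and 5.70 for the 29 falls, a difference of 0.81 (two-sided permutation test across IDs, p = 0.0398). For 577 of these 816 IDs the implied mean of the lower group was under 1, so the medians rest largely on fitted values. IDs are not independent replicates, and the difference did not pass the threshold at an adjusted p under 0.01 (difference 0.68, permutation p = 0.196) or without the lowest 25% by mean (difference 0.97, permutation p = 0.126).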

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

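Bonferroni over 17209 tests, the counts by assembly, by identical values and by level, and the over-representation tests were chosen after the data were seen. The direction of the main result was kept under each alternative run: between 96.3% and 99.5% of the listed IDs past the threshold were higher. Each alternative took all or part of the same 816 IDs, so the direction could hardly turn and this is a weak check. Counts moved more. The 787 rises became 236 with implied means of at least 1 in both groups and 186 with a mean of at least 100; the other alternatives left between 556 and 787. The 29 falls became 11 without the lowest 25% by mean, 16 and 10 at an adjusted p under 0.01 and 0.001, 8 and 7 under Bonferroni adjustment over the listed genes and over the recovered number of tests, 3 with implied means of at least 1 in both groups and 1 with a mean of at least 100. These drops follow from the construction of the alternatives, which admit fewer IDs. The minimum log2 fold change of 1 removed no ID and tests nothing. The number of over-represented lists was 1, became 0 at an adjusted p under 0.01 and 2 without the lowest 25% by mean, and stayed at 1 on the primary assembly alone and with 15000 tested genes. The difference in size between rises and falls was 0.68 at an adjusted p under 0.01 and 0.97 without the lowest 25%, past the threshold in neither; fewer falls entered both. Of 48 named IDs, 7 lost their call under a stricter adjustment: MUC12, BMP6, SOX6, MYOD1, TNNC1, RYR1 and PAX7. Other normalizations, a pseudocount, leaving out replicates and set tests with an estimated correlation were not run, and neither were other scalings of AVIL, because they need values per library; AVIL kept its call under the 4 stricter adjustments. No paired analysis was possible because the table holds no values per library. Depth per library is unknown, and levels near 0 limit the fold changes of 577 of the 816 IDs.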

Other observations

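Homeobox and SOX transcription factor genes were listed more often than a random draw would give. The families (taken from gene symbols), genes and tests of this part were all chosen after the table was seen, and log2 fold changes are those of the authors' deposited table. Because the families were chosen with these values known, their p-values are descriptive and test nothing. Counts here cover listed genes only, since changes of up to 32-fold are not seen. Of 228 annotated homeobox genes, 33 were listed as higher past the threshold and none as lower, against 9.92 to be so listed by chance (one-sided hypergeometric test over 20 families, adjusted p = 2.49e-08). Besides HOX genes they include POU4F1, a factor of sensory neurons, at a log2 fold change of 9.09 with a standard error of 0.73, EN2 of the midbrain and hindbrain at 9.38, NKX2-5 of the heart at 6.24 and MNX1 of motor neurons and pancreas at 10.14. Of 19 SOX genes 6 were listed as higher, among them SOX2 at 5.40 and SOX8 at 8.40 (hypergeometric test, adjusted p = 0.000740). Other families of such factors did not pass: the 6 GATA genes held 2 rises, GATA4 and GATA5 (adjusted p = 0.0842), the 50 forkhead genes 3 (adjusted p = 0.744) and the 13 T-box genes 1 (adjusted p = 0.771, hypergeometric test for each). Markers of the embryonic kidney line HEK293, of which 5 of 9 are listed as higher, rose in the same comparison as these families. The 514 ZNF zinc finger genes held 6, fewer than the 22.4 of a random draw.

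Potassium channel genes were also listed more often than a random draw would give, with 13 of 97 listed as higher and 1 as lower against 4.22 to be listed past the threshold by chance (hypergeometric test, adjusted p = 0.000740, descriptive as above). The same 5 of 9 HEK293 markers rose alongside them. KCNH2 had a log2 fold change of 5.39, while KCNJ16 fell by 5.80. Solute carriers stood at 17 of 374, close to the 16.3 of a random draw, and 3 of the 20 families passed the threshold. Apart from HOX genes, the rises named above started from implied control means of at most 5.31 normalized counts, and genes that are off in the control cells can reach a 32-fold change more easily than expressed genes, which the test does not correct for.

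Among the listed IDs past the threshold, rises outnumbered falls by 787 to 29. Low counts or a difference in depth are argued against as the whole cause, since 63 of the 64 IDs with implied means of at least 5 in both groups were higher, 98.4% with an exact 95% interval of 91.6% to 100%, and so are alternate loci and repeated copies, without which 96.8% of 722 IDs were higher. RNA of another cell type in the AVIL libraries stays open, because the table holds no values per library and the marker list was written after it was seen: of 9 genes known from HEK293, an embryonic kidney line widely used to produce viral vectors, 5 are listed and all are higher (IRS4, IGF2BP1, INA, LIN28B and PAX2, at implied means of 2558, 760, 242, 207 and 26.3 normalized counts), against 0.401 to be had by chance. The other 4 (NEFL, NEFM, KRT8 and KRT18) are not listed, and LIN28B is also on the rhabdomyosarcoma list. G418 selection removes cells without a resistance gene, which the derived line HEK293T carries. Added RNA alone, itself without FAM111B, would need a share of 97.2% to give the fall of FAM111B. Every listed fall exceeds 32-fold and would need a share of this order, so this value cannot weigh against a smaller share behind the rises. An effect of AVIL itself, the difference that the design names, was not tested separately and cannot be told apart from added RNA here. Nor can it be told apart from a sequence difference between the cells, or from virus infection and G418 selection if the control cells did not share them.

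Genes of the MHC and of alternate loci form the other pattern: 69 listed IDs (64 higher, 5 lower) lie outside the primary assembly annotation, and 2.41% of the 746 coding IDs on it that passed the threshold, with each set of identical values counted once, fall between 28 and 34 Mb of chromosome 6, against 1.00% of annotated coding genes, a ratio of 2.41 (exact two-sided Fisher test, p = 0.000537). They include broadly expressed genes such as PRRC2A, with a log2 fold change of 10.21 and an implied 8917 against 7.52 normalized counts, and RNF5, listed under 5 IDs with identical values. A candidate explanation is a sequence difference between the cells of the groups at these polymorphic loci, so that reads match different copies, and it stays open: only 6 of the 83 such IDs past the threshold were lower, 7.23% with an exact 95% interval of 2.70% to 15.1%, where reads moving between copies would also give falls, but how reads with several matches were counted is not given in the sources used here. Some of the 83 IDs repeat another's values, so they are not independent and the interval is too narrow. Counting of the same reads at exactly identical copies is argued against as the whole cause, since only 46.0% of the 63 outside IDs past the threshold repeat the values of another ID. Copies that share only part of their reads would not repeat values, so this share cannot decide on them. Regulation of immune genes, taken as HLA, MIC, TAP and PSMB genes, would leave out 10 of the 19 genes of the region that rose. These 10 made up 52.6% with an exact 95% interval of 28.9% to 75.6%, and PRRC2A and RNF5 are among them. The complement gene C4A is also among them, so the share depends on which genes are called immune. For C4A and for the HLA and MIC genes that rose, such regulation stays open.

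The standard error of AVIL was large for its level. Taken with the implied group means, and with the same relative spread assumed in both groups, it corresponds to a modelled variation between libraries of 44.9%. The median was 11.9% over 16 IDs with a mean of at least 500 and an implied control mean of at least 5. These are values of a model and no measured spread, since no values per library were used. Of these 16, PRRC2A and HLA-B had higher values, 79.3% and 85.1%.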
